A study of Caenorhabditis elegans with 6 samples.

How the data were processed

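RNA was sequenced from whole young adult Caenorhabditis elegans, a nematode, in 6 libraries. Per the labels, 3 came from animals with GFP fused to LARP-1 at its own locus (allele yq636) and 3 from animals with APEX2 fused to it (allele yq637). LARP-1 is an RNA-binding protein of the La-related family. APEX2 is an engineered peroxidase that, given H2O2 and a biotin-coupled aniline, attaches biotin to molecules close to it, whereas GFP has no peroxidase activity. Per the labels' protocols, animals grown at 20 °C on Escherichia coli OP50 were collected from 150 plates, kept for 2 h in 950 µl at 25 °C with biotin-aniline at 3.3 mM, and given 11 µl of 100 mM H2O2 for 2 min. RNA was then taken up in TRIzol, treated with DNase I, depleted of ribosomal RNA and made into libraries with a Vazyme kit for MGI sequencers. The titles and the series design speak of immunoprecipitation. The protocols in the labels describe no pull-down of biotin-bearing or tagged material, and an unenriched input was not analysed here, so a difference between the groups can be a difference in recovery near the tagged protein or a difference in RNA level between the strains. Any difference between the groups in culture, exact age of the young adults or library preparation cannot be told apart from that of the strains.

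The submitters' processing notes name Trim Galore, Bowtie, STAR, featureCounts and DESeq2 and the build ce11. Versions, settings, the role of each tool and the use of strand are not given in the sources used here. The deposited table lists 16262 genes, each with a signal per library that is a gene read count divided by 1 size factor for that library, which the authors deposited as normalized counts. This was read from the values: in every library 100% of the values were whole multiples of the smallest value above 0, within 0.001 of a read. The reads recovered in this way numbered 4420681, 4046444 and 3824041 for LARP-1::GFP replicates 1 to 3 and 4067144, 4868431 and 6414569 for LARP-1::APEX2 replicates 1 to 3. The listed gene with the fewest reads had 2 over the 6 libraries. Reads that fell outside the listed genes are unknown, so these totals are not the whole depth. At these totals a gene with a mean value of 10 rests on about 10 reads per library, and PCR copies could not be told from separate molecules.

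Gene names were matched to the Ensembl annotation of WBcel235, the same assembly as ce11. Of the listed genes, 15688 matched by symbol, 473 by sequence name and 12 by their position on the mitochondrial genome, and 89 had no match. All matched genes were annotated as protein-coding. Coordinates are 1-based. The reference sequence was not used here, so base composition was not examined. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and reads may be split among near-identical copies such as the histone, major sperm protein and vitellogenin genes, whose single values are therefore uncertain.

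The tested genes were those with a mean value of at least 10 over the 6 libraries, which left 10534. Values were taken as log2(value + 1) and compared between the groups with limma 3.58.1 in R 4.3.3, with a trended and robust variance prior and no covariate. Adjusted p-values are Benjamini-Hochberg values over all tested genes, from tests in both directions, with a threshold of 0.05. Differences are LARP-1::APEX2 minus LARP-1::GFP on that log2 scale, which understates the change of genes with few reads, and errors of log2 differences are standard errors. Because the values are not raw counts, the log-scale test was the main one. The quasi-likelihood test of edgeR 4.0.16 and the Wald test of DESeq2 1.42.0 were run on the recovered reads as alternatives. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 2.87 to 12.0, so none was treated as a duplicate.

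Before the data were examined, 27 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists were tested with camera in limma at its preset correlation of 0.01, adjusted over the 27 lists, and again with a correlation estimated for each list. The estimated form has only the few residual degrees of freedom of the 6 libraries. It has little power here, so a list that it does not call is not shown to be unchanged. Camera asks whether the genes of a list move relative to the other tested genes. The mitochondrial genome list had been written with worm gene names and the table uses names such as COX1, so all 12 protein-coding genes of that genome were taken. Of the other list members, 8 were not found in the table. The rule named larp-1 and the crista list, the 10 genes with the largest difference in each direction among those with a conventional symbol, an adjusted p under 0.05, a mean of at least 50 and groups that did not overlap, up to 2 members per list and direction by smallest p, and the 3 genes with the highest mean. Shares of reads were compared by an exact permutation test in both directions, for which 3 libraries against 3 cannot give less than 0.1. This test was not among those fixed beforehand. It was run only for the histone, endoplasmic reticulum, cytosolic ribosomal protein and mitochondrial genome lists, which had the smallest camera p-values. As these lists already differed between the groups, its values are no separate support.

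The procedure was tested on counts simulated from the means, library sizes and spread of these libraries, with a dispersion of 0.0149. Of 10554 genes tested there, 29 of 100 genes changed 1.5-fold and 80 of 95 changed 2-fold were called in the right direction, with 2 false calls and 0 lists called. Only these genes were changed in the simulation, so the shares called do not carry over to data with more changed genes. Genes were drawn independently, so the absence of called lists says nothing on lists of correlated genes. A single dispersion served both groups, whereas the median SD of the log2 values was 0.155 with GFP and 0.230 with APEX2. The alternatives were another pseudocount, filter, scaling or quantile normalization, quality weights per library, the replicate number as a block, the count tests above, a minimum of 2-fold, the list test fry, and leaving out each library. A correction for transcript length was added after seeing the data: a smooth curve (loess, span 0.3) of each gene's deviation from its mean against log2 exonic length was removed per library, for all tested genes but the 46 without a length. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.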

Results

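The data were normalized read counts of 16262 genes in 6 libraries of whole young adult worms, 3 with LARP-1 fused to GFP and 3 with LARP-1 fused to APEX2, all given biotin-aniline and H2O2. Between 3824041 and 6414569 reads per library lay on the listed genes, and 14668 to 15450 genes had at least 1 read. The comparison asked which RNAs differed in level between the libraries of worms with the peroxidase and those of worms with GFP, and the series title directs it to mitochondrial crista proteins. The tagged gene itself, larp-1 (WBGene00020097, chromosome III, 5008925 to 5017650, minus strand, WBcel235), had normalized counts of 2826, 3022 and 2734 with APEX2 and 2600, 2607 and 2557 with GFP. Its log2 difference of 0.14 ± 0.09 did not pass (adjusted p = 0.30), so larp-1 RNA itself was not shown to differ between the strains.

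Tested as lists at camera's preset correlation, RNAs of the secretory pathway, of nuclear-encoded respiratory complexes II to IV and ATP synthase, of crista proteins, of the cuticle and of the proteasome were higher in the LARP-1::APEX2 libraries. Those of histones, of the mitochondrial genome, of both cytosolic and mitochondrial ribosomes and of heat shock proteins were lower. No list was called with an estimated correlation, and the ribosome lists were not called once differences were corrected for transcript length (adjusted p = 0.098 for each). Among single genes, 1219 rose and 1069 fell of 10534 tested (limma, Benjamini-Hochberg), from a log2 difference of -3.42 to 2.25 with a median size of 0.66. At least 2-fold moved 182 of the risen and 304 of the fallen genes. The lists of the oocyte and of the tricarboxylic acid cycle were also higher and that of sperm lower, and list medians lay between -0.80 and 0.37. Camera called 8 lists higher and 6 lower at its preset correlation, and with an estimated correlation 0 and 0, the lowest adjusted p being 0.13. That value belonged to the histone list, whose unadjusted camera p at the preset correlation was 3.3e-18, so the estimated form had little power with 6 libraries. The gene test itself called 3575 genes at an unadjusted p under 0.05, and fry called 10 lists higher and 4 lower, not calling those of the mitochondrial genome and sperm (adjusted p = 0.057 for each) or of the cuticle (0.11). The groups did not overlap in 37.4% of the tested genes, where chance gives 10%. The first principal component, with 50.9% of the variance, separated the groups. The next component, with 19.5%, set APEX2 replicate 1 (-28.3) apart from APEX2 replicates 2 and 3 (18.4 and 17.2). Leaving out GFP replicate 1, 2 or 3 lowered the counts to 744, 783 or 612 genes higher and 664, 638 or 550 lower.

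**Figure D1:**
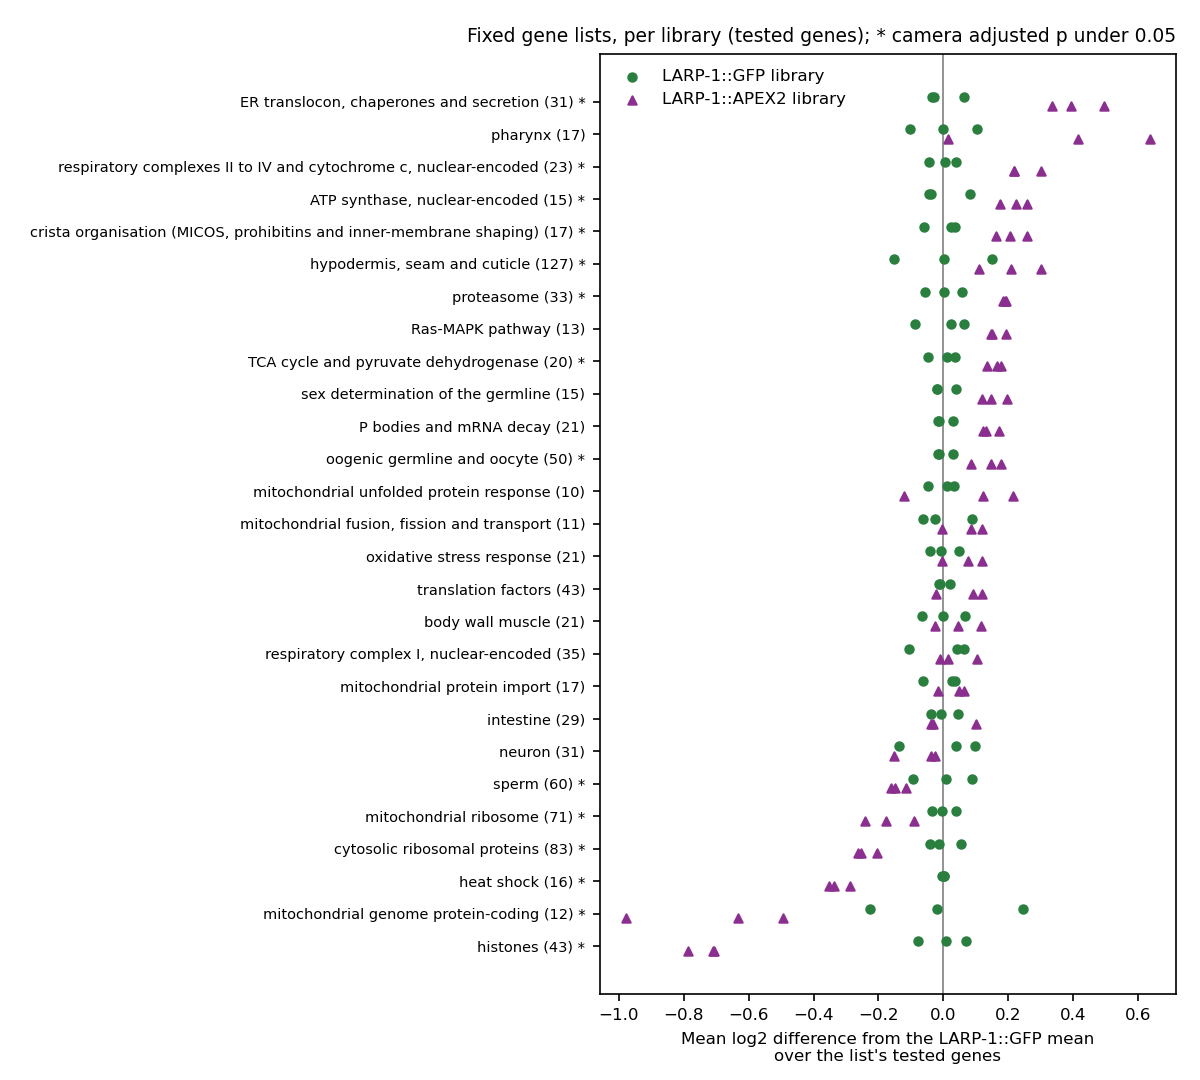
Mean log2 difference of each library from the mean of the LARP-1::GFP libraries over the tested genes of each list (number of genes in brackets), with circles for LARP-1::GFP and triangles for LARP-1::APEX2, 3 libraries each. Averaged over the LARP-1::APEX2 libraries the histone list lies lowest and the list of the endoplasmic reticulum highest, though not in each library, and the asterisks mark an adjusted p under 0.05 at camera's preset correlation, none of which held with an estimated correlation.

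Transcripts of several proteins that shape the inner mitochondrial membrane were higher with APEX2. The stomatin-like gene stl-1 (WBGene00006061, chromosome I, 9486645 to 9488029) had 454 ± 90.7 normalized counts against 261 ± 10.6 with GFP (SD, n = 3), a log2 difference of 0.78 ± 0.14 (limma, adjusted p = 0.0016). The MICOS genes moma-1 (chromosome III, 851331 to 852396) and immt-1 (chromosome X, 2682754 to 2687184), whose products hold crista junctions together, rose by 0.56 ± 0.13 (adjusted p = 0.0063) and 0.50 ± 0.15 (adjusted p = 0.026). The prohibitin gene phb-1 (chromosome I, 2071352 to 2072547) rose by 0.39 ± 0.12 (adjusted p = 0.033). The gene letm-1 (chromosome V, 13661257 to 13664233), which encodes an inner-membrane protein of ion exchange, rose by 0.41 ± 0.13 (adjusted p = 0.040). The metaxin gene mtx-2 (chromosome III, 7761977 to 7763603) fell, with a log2 difference of -0.52 ± 0.12 (adjusted p = 0.0053). The paraplegin-like protease gene spg-7 (chromosome I, 3467132 to 3478517) fell too, with -0.54 ± 0.13 (adjusted p = 0.0078). Of the 17 crista genes, 5 rose, 2 fell and 10 did not pass, although 15 had a positive difference, among them mtx-1 and F54A3.5 at 0.31, chch-3 at 0.28, phb-2 at 0.25 and immt-2 at 0.21. Adjusted over the list alone, 7 rose and 2 fell. The list median of 0.25 was called (camera adjusted p = 0.026), and the adjusted p was 0.28 with an estimated correlation. The list call ended without GFP replicate 1 (adjusted p = 0.059), with a mean of at least 50 (0.068), with edgeR (0.061) and with quantile normalization (0.13). The calls of immt-1, phb-1 and letm-1 ended without any 1 of the GFP libraries or of APEX2 replicates 1 and 2 (highest adjusted p 0.125, 0.123 and 0.134), and that of spg-7 without GFP replicate 3 (0.057). Without a GFP library the differences of immt-1, phb-1 and letm-1 still lay at 0.41 to 0.56, 0.35 to 0.43 and 0.41 to 0.42. Without APEX2 replicate 2 they were 0.52, 0.42 and 0.45. All 5 rises were largest in APEX2 replicate 1, without which the differences were 0.64 for stl-1, 0.44 for moma-1, 0.33 for immt-1, 0.25 for phb-1 and 0.26 for letm-1, and that of mtx-1, which had not passed, was 0.18.

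**Figure D2:**
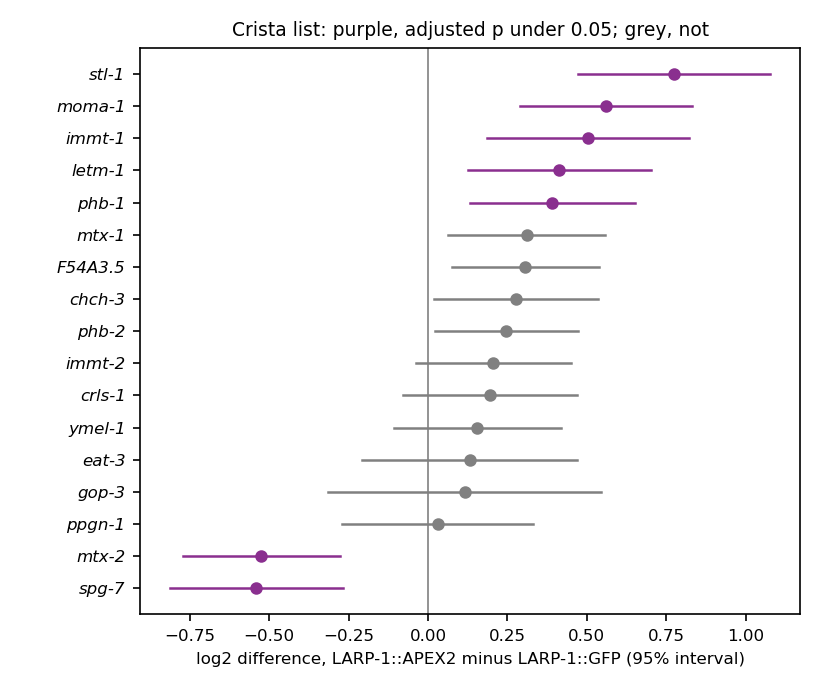
Log2 difference between LARP-1::APEX2 and LARP-1::GFP for the 17 tested genes of the crista list, with bars for the 95% confidence interval from limma and 3 libraries per group; purple genes passed and grey genes did not. The 5 genes that rose lie between 0.39 and 0.78, and mtx-2 and spg-7 lie at -0.52 and -0.54.

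Nuclear genes of complexes II to IV and of ATP synthase were higher as lists, and genes of the mitochondrial genome were lower. Of 23 nuclear genes of complexes II to IV and cytochrome c, 9 rose, 0 fell and 14 did not pass, with the same counts of 9 and 0 adjusted over the list alone. Among them cox-4, a subunit of cytochrome c oxidase, rose by 0.67 ± 0.10 (adjusted p = 0.00035) and the Rieske protein gene isp-1 by 0.56 ± 0.09 (adjusted p = 0.00075). The list median was 0.12 (camera adjusted p = 0.0039, and adjusted p = 0.28 with an estimated correlation). For ATP synthase, whose dimers line crista edges, 6 of 15 genes rose, 0 fell and 9 did not pass, and 8 rose and 1 fell adjusted over the list alone. The subunit genes asg-2 and atp-2 rose by 0.73 ± 0.10 and 0.52 ± 0.10 (limma adjusted p = 0.0003 and 0.0022), and the list median was 0.26 (camera adjusted p = 0.012, and adjusted p = 0.28 with an estimated correlation). In contrast, 8 of the 12 genes of the mitochondrial genome fell, 0 rose and 4 did not pass, with 9 lower and 0 higher adjusted over the list alone. COX1 fell to 14854 ± 2300 from 25710 ± 3301 normalized counts (SD, n = 3; limma adjusted p = 0.00054), a log2 difference of -0.79 ± 0.12, and ND6 had one of -1.42 ± 0.20 (adjusted p = 0.0003). The list median was -0.66 (camera adjusted p = 3.0e-06, and adjusted p = 0.28 with an estimated correlation), fry did not call it (adjusted p = 0.057), and the fall was largest in APEX2 replicate 1, where the list mean lay at -0.98 from the GFP mean, against -0.63 and -0.49 in replicates 2 and 3. These genes took 0.863% ± 0.160 of the reads with APEX2 and 1.41% ± 0.228 with GFP (SD, n = 3; exact permutation p = 0.1, the smallest possible). Quantile normalization ended the list calls of complexes II to IV (adjusted p = 0.13) and of ATP synthase (0.12).

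Genes of the tricarboxylic acid cycle and pyruvate dehydrogenase were higher as a list and genes of the mitochondrial ribosome lower. In the first, 6 of 20 rose, 1 fell and 13 did not pass (7 and 1 adjusted over the list alone), with dld-1 at 0.59 ± 0.11 and idha-1 at 0.50 ± 0.10, while the aconitase gene aco-2 fell with -0.73 ± 0.10. Its median was 0.19 (camera adjusted p = 0.030, and adjusted p = 0.28 with an estimated correlation). Of 71 mitochondrial ribosomal protein genes 13 fell, 0 rose and 58 did not pass, with the same counts adjusted over the list alone. The lowest by p were mrps-11 at -0.83 ± 0.12 and mrpl-38 at -1.27 ± 0.23, and the list median was -0.10 (camera adjusted p = 0.0066, and adjusted p = 0.28 with an estimated correlation). The other mitochondrial lists were not called. Of 35 nuclear genes of complex I, 6 rose, 3 fell and 26 did not pass, with the same counts adjusted over the list alone. The genes F42G8.10 and C16A3.5 rose by 0.45 and 0.36, and Y69A2AR.3 and nduf-5 fell with -0.62 and -0.51. Its median of -0.03 was negative and its mean of 0.04 positive, the direction camera gave (adjusted p = 0.61, and adjusted p = 0.82 with an estimated correlation). Of 17 protein import genes, 3 rose, among them tin-44 (0.58) and tomm-7 (0.52), 1 fell, tin-9.1 (-0.65), and 13 did not pass, with 4 and 2 adjusted over the list alone. Their median of 0.01 turned negative under each rescaling and under quantile normalization (camera adjusted p = 0.62, and adjusted p = 0.76 with an estimated correlation). Of 11 genes of fusion, fission and transport, the fission dynamin gene drp-1 (0.55) and miro-1 (0.53) rose, mff-2 (-0.47) fell and 8 did not pass, with 2 and 1 adjusted over the list alone, around a median of 0.12 (camera adjusted p = 0.53, and adjusted p = 0.65 with an estimated correlation). In the mitochondrial unfolded protein response, 3 of 10 rose, among them gpd-2 (0.66) and the protease gene lonp-1 (0.58), 1 fell, ubl-5 (-0.84), and 6 did not pass, with 3 and 2 adjusted over the list alone. Its median was 0.07 (camera adjusted p = 0.53, and adjusted p = 0.74 with an estimated correlation). The call of the tricarboxylic acid cycle ended without GFP replicate 3 (adjusted p = 0.064) or APEX2 replicate 2 (0.053) and under 5 of the other settings, among them edgeR (0.071), DESeq2 (0.053) and quantile normalization (0.28). Among the genes, the calls of mff-2 and ubl-5 ended without GFP replicate 1 (adjusted p = 0.106 and 0.162), that of C16A3.5 without GFP replicate 2 (0.075), those of nduf-5 and lonp-1 without GFP replicate 3 (0.147 and 0.052) and that of Y69A2AR.3 without APEX2 replicate 2 (0.089). Corrected for length, Y69A2AR.3 and nduf-5 had differences of -0.31 and -0.28, and without APEX2 replicate 1 nduf-5 had one of -0.30.

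Short genes were lower with APEX2 in all 3 libraries. In the 10% of the tested genes with the least exonic sequence, 30 to 568 nucleotides, the median log2 difference was -0.27, and 65 genes rose and 273 fell. Its median against the GFP mean was -0.28, -0.27 and -0.22 in the APEX2 libraries and between -0.01 and 0.03 in the GFP libraries. In the next 10% the median was -0.06, and in the others it lay between 0.01 and 0.08. The lists with the shortest genes, with a median exonic length of 384 nucleotides for sperm, 408 for histones and 530 for cytosolic ribosomal proteins, were all called lower. Among the next, the mitochondrial ribosome (755) was called lower, complexes II to IV (728) and ATP synthase (735) were called higher, and complex I (732) and protein import (736) were not called. With differences corrected for length, the median for complexes II to IV was 0.42 (camera adjusted p = 7.0e-06) and for ATP synthase 0.28 (0.0011). The crista list stayed called at 0.20 (adjusted p = 0.048). With an estimated correlation none of these held after the correction (adjusted p = 0.24, 0.24 and 0.35). The lists of the mitochondrial ribosome at -0.06 (adjusted p = 0.098) and the tricarboxylic acid cycle at 0.13 (0.13) were no longer called, although 12 genes of the mitochondrial ribosome were still lower and 0 higher. Corrected in the same way, immt-1, phb-1, letm-1 and the import gene tin-9.1 no longer passed (limma adjusted p = 0.050, 0.057, 0.087 and 0.107), with differences of 0.44, 0.34, 0.35 and -0.33.

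**Figure D3:**
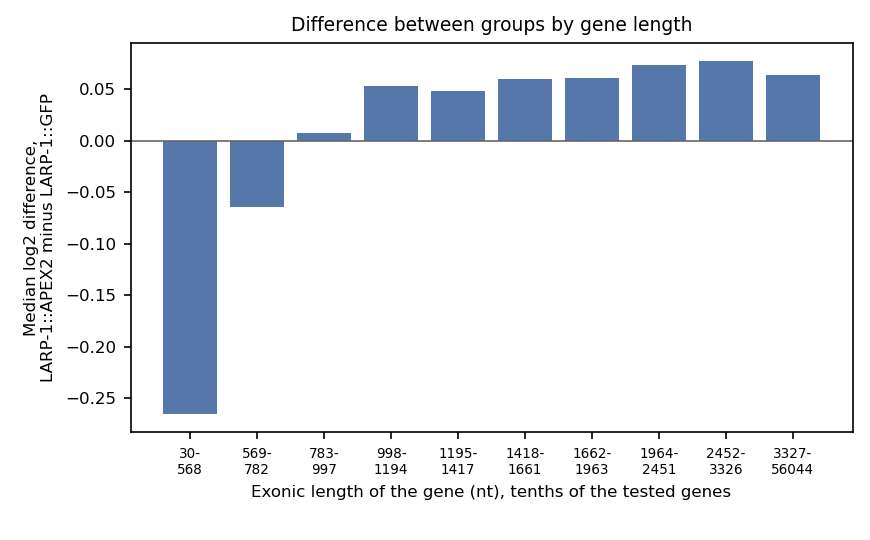
Median log2 difference between LARP-1::APEX2 and LARP-1::GFP (bars, from 0) for the tested genes in 10 groups of like size by exonic length in nucleotides, 3 libraries per group. The group of the shortest genes lies at -0.27 and the groups from 783 nucleotides upward between 0.01 and 0.08.

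Transcripts of cytosolic ribosomal proteins were lower with APEX2, while those of translation factors and of P bodies, the granules of mRNA decay, were not called as lists. Of 83 ribosomal protein genes 31 fell, 3 rose and 49 did not pass, with 33 and 3 adjusted over the list alone. The genes ubl-1, which encodes a ubiquitin-like fusion to a ribosomal protein, and rpl-39 fell, with -0.92 ± 0.10 (limma adjusted p = 3.5e-05) and -0.77 ± 0.09 (adjusted p = 0.0001), and rpl-18 and rpl-25.2 rose by 0.28 and 0.33. The list median was -0.23 (camera adjusted p = 1.1e-07, and adjusted p = 0.20 with an estimated correlation), and the genes took 12.33% ± 0.149 of the reads with APEX2 and 14.1% ± 0.322 with GFP (SD, n = 3; exact permutation p = 0.1). Of 43 translation factors, 11 rose, 2 fell and 30 did not pass (12 and 2 adjusted over the list alone). The elongation factor gene eef-1A.2 and the eIF5A gene iff-2 rose by 0.54 and 0.55, and the germline genes ife-1, of the eIF4E family, and iff-1 fell with -0.97 and -0.82. Their median of 0.03 turned negative when libraries were scaled to the same total or quantile normalized (camera adjusted p = 0.25, and adjusted p = 0.55 with an estimated correlation). Of 21 genes of P bodies and mRNA decay, larp-1 among them, 6 rose, among them the decapping gene edc-3 (0.60) and gtbp-1 (0.56), 1 fell, tiar-1 (-0.31), and 14 did not pass, with 6 and 2 adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.083, and adjusted p = 0.28 with an estimated correlation). Corrected for length, the ribosomal protein list had a median of -0.09 and was no longer called (adjusted p = 0.098), with 10 genes higher and 19 lower. The P body list was not called with that correction (camera adjusted p = 0.18). Without the correction and without a filter on low values it was called (0.020). The calls of rpl-18, rpl-25.2 and tiar-1 ended without any 1 of the GFP libraries and without APEX2 replicate 2 (highest adjusted p 0.119, 0.144 and 0.154).

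Histone transcripts had the lowest list median before correction for length. Of 43 histone genes 26 fell, 1 rose and 16 did not pass, and adjusted over the list alone 30 fell and 1 rose. The gene his-16 fell to 114 ± 5.99 from 428 ± 60.3 normalized counts (SD, n = 3; limma adjusted p = 1.7e-06), a log2 difference of -1.89 ± 0.14, and his-1 had one of -1.54 ± 0.12 (adjusted p = 4.7e-06). The gene that rose was his-41, by 0.48 ± 0.13 (adjusted p = 0.019), a call that ended without GFP replicate 2 or 3 or APEX2 replicate 2 (highest adjusted p 0.106). The list median was -0.80 (camera adjusted p = 9.0e-17, and adjusted p = 0.13 with an estimated correlation), and -0.62 when corrected for length (adjusted p = 4.2e-10), where that of the mitochondrial genome was lower, at -0.68. Summed over copies, which does not depend on how reads were split among them, histones took 0.977% ± 0.0177 of the reads with APEX2 and 1.65% ± 0.0870 with GFP (SD, n = 3; exact permutation p = 0.1).

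Genes of protein entry into the endoplasmic reticulum, folding and secretion had the highest list median before correction for length, and 0.31 against 0.42 for complexes II to IV after it. Of 31 such genes 18 rose, 0 fell and 13 did not pass, with the same counts adjusted over the list alone. The translocon-associated genes trap-2 and trap-3 rose by 1.42 ± 0.13 (limma adjusted p = 9.4e-06) and 0.96 ± 0.12 (adjusted p = 8.5e-05), and trap-2 (chromosome X, 767023 to 768069) reached 2889 ± 523 normalized counts from 1073 ± 131 (SD, n = 3). The list median was 0.37 (camera adjusted p = 2.6e-08, and adjusted p = 0.20 with an estimated correlation), and these genes took 1.501% ± 0.0693 of the reads against 1.08% ± 0.0320 (SD, n = 3; exact permutation p = 0.1). Of 33 proteasome genes 11 rose, 1 fell and 21 did not pass (13 and 1 adjusted over the list alone). The regulatory subunit genes rpn-1 and rpt-4 rose by 0.79 ± 0.10 and 0.72 ± 0.12, and the core gene pas-7 fell with -0.49 ± 0.10, around a median of 0.17 (camera adjusted p = 0.0045, and adjusted p = 0.28 with an estimated correlation). Heat shock genes were lower as a list: 8 of 16 fell, 3 rose and 5 did not pass, with the same counts adjusted over the list alone. The small heat shock genes hsp-16.2 and hsp-12.6 fell, with -0.83 ± 0.10 and -1.37 ± 0.18, whereas the chaperone gene hsp-90 and the gene of the heat shock factor, hsf-1, rose by 0.43 and 0.45. The median was -0.32 (camera adjusted p = 0.0066, and adjusted p = 0.20 with an estimated correlation). Of 21 genes of the oxidative stress response, which H2O2 can induce, 3 rose, 3 fell and 15 did not pass, with 4 and 4 adjusted over the list alone. The glutathione transferase gene gst-38 (1.61) and the peroxiredoxin gene prdx-2 (0.37) rose, and sqst-1 (-0.54) and the superoxide dismutase gene sod-2 (-0.47) fell. Its median was -0.06 and its mean 0.06, the direction camera gave (adjusted p = 0.99, and adjusted p = 0.99 with an estimated correlation). Quantile normalization ended the proteasome call (adjusted p = 0.30), leaving out GFP replicate 3 ended those of hsf-1 and prdx-2 (0.092 and 0.066), and leaving out APEX2 replicate 2 ended that of sod-2 (0.105).

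Germline genes moved in both directions. Of 50 oocyte and oogenic germline genes 18 rose, 3 fell and 29 did not pass (19 and 3 adjusted over the list alone). The RNA-binding protein gene puf-7 and egg-1, which encodes an egg surface protein, rose by 0.73 ± 0.11 and 0.61 ± 0.11, and the P granule gene pgl-1 and the yolk receptor gene rme-2 fell with -1.02 ± 0.12 and -0.34 ± 0.10. The median was 0.11 (camera adjusted p = 0.0066, and adjusted p = 0.28 with an estimated correlation). Of 60 sperm genes 11 fell, 2 rose and 47 did not pass (13 and 2 adjusted over the list alone). Those named by the rule were msd-4 (-0.91) and nspd-2 (-0.89) among the fallen, and msp-57 (0.50) and ssp-9 (1.24), the risen ones. The median was -0.13 (camera adjusted p = 0.046, and adjusted p = 0.43 with an estimated correlation). Of 15 sex determination genes mog-1 (0.46) and fog-1 (0.61) rose, tra-1 (-0.35) fell and 12 did not pass, with 0 and 0 adjusted over the list alone, around a median of 0.16 (camera adjusted p = 0.14, and adjusted p = 0.28 with an estimated correlation). Of 13 Ras-MAPK genes the Raf gene lin-45 (0.42) rose, 0 fell and 12 did not pass, with 1 and 0 adjusted over the list alone, around a median of 0.17 (camera adjusted p = 0.13, and adjusted p = 0.28 with an estimated correlation). Corrected for length, the oocyte list (median 0.05, adjusted p = 0.098) and the sperm list (median 0.08, adjusted p = 0.21, thus of the opposite sign) were no longer called. Quantile normalization also ended the oocyte call (adjusted p = 0.25) and the sperm call (0.090). Leaving out GFP replicate 1 or 2 or APEX2 replicate 2 or 3 ended the sperm call too (highest 0.13), as edgeR (0.068) and DESeq2 (0.064) did. No filter on low values (0.093) and quality weights per library (0.056) ended it as well. Among the genes, the calls of rme-2, ssp-9 and fog-1 ended without GFP replicate 3 (adjusted p = 0.145, 0.052 and 0.187), that of mog-1 without GFP replicate 1 (0.147), that of tra-1 without GFP replicate 2 (0.190), that of lin-45 without APEX2 replicate 2 (0.078) and that of nspd-2 with the length correction (0.11).

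Among the somatic tissues, the list of the hypodermis and its cuticle was called higher with APEX2. Of 127 such genes 32 rose, 7 fell and 88 did not pass, and 38 rose and 7 fell adjusted over the list alone. The collagen genes col-143 and col-17 rose by 1.56 ± 0.11 and 1.89 ± 0.21 (limma adjusted p = 1.7e-06 and 5.5e-05), whereas col-135 and col-153 fell, with -2.89 ± 0.30 and -0.99 ± 0.17 (adjusted p = 3.0e-05 and 0.00088). The median was 0.24 (camera adjusted p = 0.0020, and adjusted p = 0.54 with an estimated correlation; fry adjusted p = 0.11). The list means of the libraries overlapped, at 0.21, 0.30 and 0.11 from the GFP mean with APEX2 and 0.15, 0.00 and -0.15 with GFP. Markers of the other somatic tissues were not called. Of 17 pharynx genes 4 rose, among them abu-1 (1.16) and phat-4 (0.76), 0 fell and 13 did not pass, with 5 and 0 adjusted over the list alone. Their median was 0.28 (camera adjusted p = 0.083, and adjusted p = 0.65 with an estimated correlation), and the means of the 3 APEX2 libraries lay far apart, at 0.64, 0.41 and 0.01 above the GFP mean. Of 21 body wall muscle genes the tropomyosin gene lev-11 (0.62) and unc-60 (0.58) were among 4 that rose, unc-22 (-0.73) and the myosin gene myo-3 (-0.53) fell, and 15 did not pass, with 4 and 3 adjusted over the list alone. Their median of 0.15 turned negative under quantile normalization (camera adjusted p = 0.29, and adjusted p = 0.74 with an estimated correlation). Of 29 intestine genes 11 rose, 7 fell and 11 did not pass, with 11 and 7 adjusted over the list alone. The yolk protein genes vit-4 and vit-1 rose by 1.11 ± 0.10 and 1.01 ± 0.11, and the protease gene cpr-1 and the metallothionein gene mtl-1 fell with -1.73 ± 0.11 and -1.82 ± 0.17. The median was -0.03 and the mean 0.01, the direction camera gave (adjusted p = 0.53, and adjusted p = 0.76 with an estimated correlation). Of 31 neuron genes flp-9 (0.54) and unc-18 (0.40) rose, 0 fell and 29 did not pass, with 0 and 0 adjusted over the list alone, around a median of -0.09 (camera adjusted p = 0.63, and adjusted p = 0.77 with an estimated correlation). The pharynx list was called without APEX2 replicate 3 (median 0.51, adjusted p = 0.0075), without GFP replicate 1 (0.043) and without a filter on low values (0.024). Leaving out GFP replicate 3 ended the calls of myo-3 and unc-18 (0.096 and 0.155), and leaving out GFP replicate 1 ended that of flp-9 (0.149). The call of unc-18 also ended with no filter on low values (adjusted p = 0.060), scaling to the same total (0.081), TMM (0.052), the replicate block (0.080), DESeq2 (0.069) and the length correction (0.087).

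The largest differences are given here for genes with a conventional symbol, a mean of at least 50 normalized counts and groups that did not overlap, and some genes outside these limits differed by more. Besides col-17, col-143 and trap-2, the 10 of them that rose most were the choline kinase gene ckb-2 (1.53 ± 0.20), hacd-1 (1.51 ± 0.14), tag-10 (1.497 ± 0.256), abhd-3.2 (1.45 ± 0.19), cdr-4 (1.40 ± 0.15), the cystathionine lyase gene cth-1 (1.34 ± 0.11) and the galectin gene lec-10 (1.30 ± 0.11). The saposin-like gene spp-2 (chromosome X, 7315995 to 7316818) fell most of them, to 64.05 ± 11.1 from 298 ± 16.5 normalized counts (SD, n = 3; limma adjusted p = 1.7e-06), a log2 difference of -2.21 ± 0.16. Besides his-16, mtl-1 and cpr-1, the others were cest-12 (-1.89 ± 0.23), the ubiquitin ligase gene siah-1 (-1.79 ± 0.11), the lipase gene lipl-2 (-1.79 ± 0.16), scl-2 (-1.73 ± 0.15), wdr-46 (-1.66 ± 0.22) and rsks-1 (-1.59 ± 0.16), which encodes the S6 kinase that acts on ribosomes. The least significant of these 20 genes, tag-10, had an adjusted p of 0.0011. The genes with the most reads differed little: the protease gene asp-1 fell with -0.32 ± 0.11 (adjusted p = 0.044), a call that ended without any 1 of the GFP libraries or of APEX2 replicates 2 and 3 (highest adjusted p 0.165), under the replicate block (0.064) and under quantile normalization, which left -0.14 (0.38). The adenine nucleotide carrier gene ant-1.1 (0.23 ± 0.08, adjusted p = 0.068) and the elongation factor gene eef-1A.1 (0.00 ± 0.09, adjusted p = 0.99) did not pass.

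**Figure D4:**
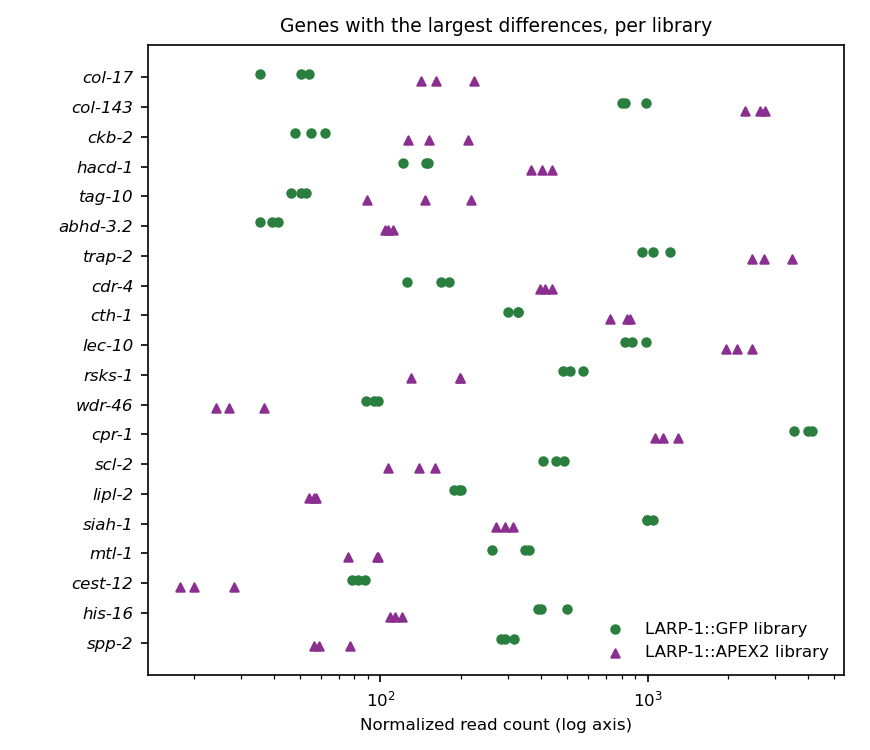
Normalized read count (log axis) in each library for the 10 genes that rose most and the 10 that fell most among those chosen by the naming rule, with circles for LARP-1::GFP and triangles for LARP-1::APEX2, 3 libraries each. For all 20 genes the libraries of the groups do not overlap, as the rule required, and spp-2 shows the largest fall, from 298 to 64.05.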

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

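Of the settings given here, the transcript length correction was chosen after seeing the data. The counts of 1219 genes higher and 1069 lower stayed within 1.5 times under both other pseudocounts, both other filters, both rescalings, quantile normalization, quality weights, edgeR (1127 and 1096 genes, keeping 94.97% of the calls) and DESeq2 (1034 and 958, keeping 85.9%). A minimum of 2-fold left 182 and 304, and leaving out 1 library gave 612 to 1310 genes higher and 550 to 1191 lower. Scaling to the same total moved the share of higher genes from 53.3% to 44.2% of the calls. The lists called higher fell from 8 to 2 under quantile normalization, those called lower from 6 to 3 with the length correction, and both to 0 with an estimated correlation. The estimated correlations of the heat shock and tricarboxylic acid cycle lists, -0.0633 and 0.0062, lay below the preset 0.01, yet these calls ended too. For these lists a higher correlation thus does not account for the loss. With an estimated correlation camera uses the few residual degrees of freedom of the 6 libraries, and with a preset one those of the many genes. Calls that ended under this setting therefore do not by themselves show correlated genes. The replicate number as a block gave 984 genes higher and 883 lower and 9 and 6 lists. Same-numbered libraries did not deviate together (residual correlations -0.16, -0.08 and 0.02), so no effect shared by number was seen. So few libraries cannot show that same-numbered samples were handled apart, and the labels do not say. Under the block the pharynx list gained a call (camera adjusted p = 0.041) and 9 of the 109 named called genes lost theirs. Of these 109 genes, 28 lost their call without at least 1 library and 11 with the length correction, in none did the sign turn under a setting that was run, and 79 kept their call under each of them. For genes whose call ended without more than 1 library, the one with the highest adjusted p is given above. Fewer libraries can also lower the power of the test, so a call that ended in this way need not rest on the library left out. Quantile normalization ended the calls of asp-1, C16A3.5, phb-1, rpl-18, letm-1 and lin-45 (adjusted p from 0.051 to 0.38), scaling to the same total those of unc-18, rpl-18, mog-1, letm-1 and fog-1 (0.051 to 0.081), TMM that of unc-18, DESeq2 those of unc-18 and mog-1, quality weights that of tra-1 (0.077) and no filter that of unc-18. The block ended those of asp-1, letm-1, mog-1, rme-2, rpl-18, rpl-25.2, tiar-1, tra-1 and unc-18 (0.055 to 0.087). The length correction ended those of nduf-5, Y69A2AR.3, ubl-5, nspd-2, tin-9.1, unc-18, letm-1, mog-1, fog-1, phb-1 and immt-1 (0.050 to 0.26). Of these, the differences of nspd-2 (-0.39), Y69A2AR.3 (-0.31), nduf-5 (-0.28), ubl-5 (-0.50) and tin-9.1 (-0.33) shrank by more than 1.5 times, and the others, such as fog-1 (0.56), mog-1 (0.39) and unc-18 (0.33), did not. The correction also moved called genes that stayed called by more than 1.5 times, rpl-39 to -0.30, msd-4 to -0.58, rpl-25.2 to 0.51, msp-57 to 0.77 and tomm-7 to 0.90, and F54A3.5 passed with it (0.52, adjusted p = 0.0040). Lists and genes that were not called turned in sign as follows, for causes not tested. Scaling to the same total gave -0.0548 for eef-1A.1, -0.0445 for protein import and -0.0229 for translation factors, and scaling by TMM gave -0.0186 and -0.0085 for the first 2. Quantile normalization gave -0.0214 for eef-1A.1, -0.0137 for import, -0.0261 for translation factors and -0.0236 for body wall muscle. For eef-1A.1 edgeR gave -0.0156 and DESeq2 -0.0128. The length correction gave -0.0553 for eef-1A.1, 0.0769 for complex I, -0.0241 for translation factors, 0.0184 for oxidative stress and 0.0848 for sperm, a list whose call it ended. Quality weights gave 0.0133 for complex I, and a mean of at least 50 gave 0.126 for intestine and 0.0166 for neuron. Without 1 library, eef-1A.1 ranged from -0.0631 to 0.0447, complex I from -0.0262 to 0.0305, import from -0.0451 to 0.0812 and the mitochondrial unfolded protein response from -0.0773 to 0.323. Translation factors ranged from -0.0143 to 0.109, intestine from -0.0979 to 0.0410 and oxidative stress from -0.0614 to 0.0830. The neuron list stayed negative without any single library, but ranged from -0.175 to -0.0060. Depth limits the genes with few reads, and 3 libraries per group limit small differences.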

Other observations

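The tests of gene families, of chromosomes, of the length correction and of the whole set of nuclear respiratory genes were chosen only after the results were seen. Those of read shares and of the DNA replication and cell division genes were not among the tests fixed beforehand either. Families sharing a gene name were tested with camera where at least 8 members were tested, which gave 125 families, of which 6 were called higher and 7 lower after adjustment over them. Only 5 were called with the length correction, and the lowest adjusted p with an estimated correlation was 0.48. The 5 were the histones, vha, abu, elo and sec. Of the 20 vha genes, of the V-ATPase, the proton pump of lysosomes and other acid compartments, 14 rose and 1 fell, with a median log2 difference of 0.49 (camera adjusted p = 2.1e-06, and adjusted p = 0.71 with an estimated correlation), and it stayed called with the length correction (2.9e-07). Under each setting run its median lay between 0.374 and 0.544. The genes vha-12 and vha-8, named after their values were seen, rose by 0.93 ± 0.09 and 0.87 ± 0.11 (limma adjusted p = 2.1e-05 and 0.00016), and vha-7 fell with -0.42 ± 0.11 (adjusted p = 0.013), a call that ended without GFP replicate 2 (0.070) or 3 (0.071) or APEX2 replicate 2 (0.058). The abu genes, among them abu-1 of the pharynx list, had the largest median, 0.98, with 6 of 10 risen and 0 fallen (camera adjusted p = 0.0016, and adjusted p = 0.71 with an estimated correlation). Of 19 sec genes, some of them in the list of the endoplasmic reticulum, 5 rose and 0 fell, with a median of 0.21 (camera adjusted p = 0.017, and adjusted p = 0.71 with an estimated correlation), a call that a mean of at least 50 ended (0.052). The sec median lay between 0.157 and 0.336 under the settings run, the highest without APEX2 replicate 3. Of the fatty acid elongases, 6 of 9 elo genes rose and 0 fell, with a median of 0.68 (camera adjusted p = 0.0094, and adjusted p = 0.71 with an estimated correlation), and elo-2 and elo-1 rose by 1.25 ± 0.11 and 0.90 ± 0.15. At the preset correlation vha, abu and elo stayed called under each setting in which camera was rerun (highest adjusted p 0.00020, 0.021 and 0.019). Of 8 rsp genes, which encode SR splicing factors, 5 rose and 0 fell, with a median of 0.42 (camera adjusted p = 0.039, and adjusted p = 0.71 with an estimated correlation), rsp-6 by 0.64 ± 0.10 and rsp-2 by 0.73 ± 0.14, but the length correction (adjusted p = 0.14), quantile normalization, a mean of at least 50 and leaving out GFP replicate 1 or APEX2 replicate 2 ended the call (highest 0.19). Of 15 saposin-like spp genes 6 fell and 0 rose, with a median of -0.36 (camera adjusted p = 0.019, and adjusted p = 0.71 with an estimated correlation), a call that ended with the length correction (median -0.0706, adjusted p = 0.36) and without APEX2 replicate 1 (-0.177, 0.066), while without APEX2 replicate 2 the median was -0.179 and the call stayed. None of these 6 families changed the sign of its median under a setting that was run.

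The X chromosome held more risen than fallen genes, 184 against 101 of 1408 tested, with a median of 0.13 (Fisher's exact test of higher against lower calls, adjusted p = 0.00036 over 6 chromosomes). Of the genes named above, vit-4, vit-1, trap-2, asg-2 and gpd-2, which rose, and spp-2, which fell, lie there, among others. For each autosome the adjusted p was 0.70. The X chromosome kept a positive median under each setting, and its excess of higher calls stayed when libraries were scaled to the same total (145 higher, 110 lower, adjusted p = 0.00013), by TMM (0.00044) or quantile normalized (4.6e-07). The test no longer called it without any 1 of the GFP libraries or of APEX2 replicates 1 and 2, with adjusted p from 0.0935 to 1, although higher calls outnumbered lower ones in each of these, as with 164 against 114 without APEX2 replicate 1, and the median lay between 0.104 and 0.138. The test treats genes as independent, which genes on a chromosome are not.

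Lower histone transcripts with APEX2 are not accounted for by the trend with length alone, since the list kept a median of -0.618 after that trend was removed. A fall of the whole replication program was not seen, as 31 genes of DNA replication and cell division had a median of 0.0371. The 95% interval was -0.0738 to 0.152 (bootstrap over genes and not libraries), with 2 risen and 1 fallen. Such genes can also be expressed in cells that do not divide, so these values cannot exclude fewer dividing cells. Reads moved between near-identical copies would leave the sum as it was, but all histone genes together took 0.977% of the reads with APEX2 against 1.65% with GFP, with no overlap. Reads left out because they map to several copies would change the sum, and their treatment is not given, so this cannot be excluded. The replication-independent variant his-72 had a difference of 0.40 ± 0.18 that did not pass (limma adjusted p = 0.13, and 0.0019 without APEX2 replicate 3). Its normalized counts were 3747, 2781 and 1869 with APEX2 and 1912, 1999 and 2207 with GFP, so APEX2 replicate 3 lay below each GFP library. The genes his-71 (0.16), his-70 (0.28) and his-74 (-0.01) did not pass either. The linker histone genes hil-1 and hil-4 fell with -1.55 ± 0.18 and -0.61 ± 0.10 (limma adjusted p = 7.5e-05 and 0.00075). The genes hil-2 (-0.33) and hil-3 (-0.46) did not pass. A candidate explanation is a difference in how the mostly tail-less histone mRNAs were kept, recovered or made in the strains, which stays open and was not tested. Whether the linker histone mRNAs are tail-less was not examined, so this explanation need not cover the fall of hil-1 and hil-4.

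The lower cytosolic ribosomal protein transcripts may be part of the trend with length. Once this trend was removed the list median moved from -0.23 to -0.0851 and the list was no longer called (camera adjusted p = 0.098), with 10 genes risen and 19 fallen. Ribosomal protein mRNAs are known targets of LARP-1 proteins in other animals, so a difference tied to LARP-1 stays open beside it, untested, as does the reason for the trend, which could be in RNA integrity, fragment size or clean-up of the libraries.

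Lower transcripts of the mitochondrial genome are not accounted for by length alone, since their median was -0.676 after the correction. A fall shared by nuclear-encoded mitochondrial transcripts was not seen in the 73 nuclear genes of the respiratory chain and ATP synthase. Their median was 0.130 (95% interval 0.0055 to 0.205, bootstrap over genes and not libraries), with 21 risen and 3 fallen. The set includes the lists of complexes II to IV and of ATP synthase, which had already been called higher. Of the 71 nuclear genes of the mitochondrial ribosome, in contrast, 13 fell and 0 rose. With the length correction 12 were lower and 0 higher, though that list was then no longer called. Nuclear genes are transcribed apart from the mitochondrial genome and need not follow the number of mitochondria. These values therefore cannot decide whether there were fewer mitochondria. What stays open, untested, is whether the strains differed in mitochondrial transcript level or the libraries in how mitochondrial RNA was recovered. A difference in recovery would be consistent with a peroxidase that labels the cytosol and not the matrix, but the labels describe no capture step against which to test it.

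The 6 libraries can be divided into 3 and 3 in 10 ways. Only 1 of the 10, the real one, gave as many as 1219 genes higher or 1069 lower, and the highest count in either direction in the others was 0. Each of the other splits mixes libraries of both strains in each set, so a difference between the strains adds to the spread within a set. Their count of 0 therefore does not show how many genes a grouping without such a difference would give. With 10 splits no share under 0.05 can be reached.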
